A study of Mus musculus with 4 samples.

How the data were processed

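RNA from punches of the medial prefrontal cortex of male mice on postnatal day 90 was measured on Affymetrix 3' expression arrays, with total RNA carried through biotin labelling, per the labels' protocols. The 4 arrays fell into 2 groups by the treatment label: 2 from mice exposed to fluoxetine before birth and 2 from untreated mice. Replicates were numbered by their order within a group, so that no number pairs arrays between groups, and the fits held no pairing. The labels call the arrays of a group biological duplicates.

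The deposited values were log2 intensities per probe set, made by the authors with RMA through the affy package, and limma is also named, per the submitters' processing notes; no versions are given in the sources used here. The lowest values lie below those that plain RMA usually gives, and whether another background correction was applied is not given in the sources used here. The log base was read from the values, which ran from −0.08 to 15.14, and the array quartiles differed slightly (lower quartiles 4.42 to 4.57, upper quartiles 8.68 to 8.78). The value table held 45101 probe sets, of which 64 were array controls. Gene names came from the platform annotation matched to the table. In it 34945 probe sets had 1 gene symbol and were tested, 932 had several symbols and were named for none of them, and 9160 probe sets other than controls had no row and are unnamed here. Of the tested probe sets, 34741 matched a mouse gene by Entrez number in the RefSeq table of assembly GRCm38.p6, and 0 symbols needed updating. Genome positions were not used here, because no build is given in the sources used here.

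Each gene was represented by its probe set with the highest mean over the 4 arrays, which gave 18193 genes, and no filter on low values was applied. Fluoxetine was compared with untreated on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The design leaves 2 residual degrees of freedom. The p-values measure the spread between these arrays, with each gene's variance drawn toward that of genes of like intensity. The fit had 5.15 prior degrees of freedom beside the 2 residual ones, so most of each variance came from other genes. A difference is the mean of the fluoxetine arrays minus that of the untreated arrays, and its SE is the moderated one of limma. Differences of log2 intensities can understate those of dim transcripts, because background adds to every probe set, and can overstate them where the background correction subtracted too much.

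Gene lists for synaptic, neuronal, glial, vascular, neighbouring-tissue, stress and clock transcripts were fixed before the data were examined, 31 in all, with 713 entries, of which 76 had no named probe set and were not analysed here. Lists with at least 5 measured members were tested with limma's camera, with a preset correlation between genes of 0.01 and an intensity trend, and adjusted over all lists. Camera with a correlation estimated for each list and fry, which tests whether a list's genes move on balance one way, were alternatives. None of the 10 lists past the threshold passed with an estimated correlation, where the lowest adjusted p was 0.654, and 1 passed with fry. Estimating the correlation also makes camera refer its statistic to the 2 residual degrees of freedom, where few lists can pass. The estimated correlation was −0.06 for clock genes and −0.03 for superficial-layer markers, below the preset 0.01. For these lists correlation between members therefore did not end the call. For the other lists past the threshold it was above the preset, such as 0.06 for chaperones, 0.14 for immediate early genes and 0.75 for striatal markers. In those lists the higher correlation and the few degrees of freedom were not told apart.

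The genes named in the text followed a rule set before the data were examined: every gene at an adjusted p below 0.05; then, up to 12 per direction, those with the largest log2 difference among genes at an unadjusted p below 0.05 whose groups did not overlap and whose mean lay above the median of all tested genes; up to 4 members with the smallest p of each list past its threshold; and a fixed set of serotonin, GABA, interneuron, inhibitory synapse and activity genes. Some genes of the fixed set had no named probe set and were not analysed here. The sex-linked genes and the array controls were described per array and not tested.

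The code was tested on simulated data for the comparison of fluoxetine with untreated: in 20 draws over 18193 genes with normal noise of the fitted size, 200 genes per draw were changed. At an adjusted p below 0.05 the fit called 71.5% of the genes changed 1.5-fold, 96.2% of those changed 2-fold and 99.9% of those changed 3-fold. A list shifted by 0.1 on the log2 scale was called in 20 of 20 draws, and 2 of 600 lists without a shift were called. The simulated genes were independent of each other, which real genes of a list are not. Their noise had the moderated variances of limma, already drawn together across genes, and no variation shared by an array. The percentages therefore test the code and do not show that real changes of 1.5-fold or 2-fold would be called. In the data Malat1, at 1.97-fold, had a limma adjusted p of 0.666.

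Alternatives were eBayes without the trend, eBayes with trend and robust estimation, array weights, quantile normalization of the deposited values, subtraction of array medians, a filter at the median level, the mean of all probe sets or the most variable probe set of a gene, all probe sets with unnamed ones included, fold thresholds of 1.2 and 2, the other list tests, and leaving out each array in turn. When 1 array of a group is left out, the lone array is assumed to vary like the arrays of the other group.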

Results

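Transcript levels were measured in the prelimbic cortex, the part of the medial prefrontal cortex that serves working memory and social behaviour in rodents, of male mice on postnatal day 90. The mice had been exposed before birth to fluoxetine, a selective serotonin reuptake inhibitor, or were untreated. Each group held 2 arrays, described by the submitters as biological duplicates, and the labels do not say whether an array held 1 mouse or a pool, nor whether the mice of a group came from separate litters. The 4 arrays had median log2 intensities of 6.44 and 6.47 with fluoxetine and 6.50 and 6.48 without. Over all probe sets the arrays correlated at 0.997 within the fluoxetine group, 0.996 within the untreated group and 0.996 to 0.997 between groups, so that the groups were about as far apart as arrays of the same group. The number of arrays limits the precision: an exact two-sided permutation test of 2 against 2 cannot give a p below 0.333. The male label was checked first. Transcripts of the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 6.83 and 8.59 on all 4 arrays, and Xist, the noncoding RNA of the inactive X chromosome, between 5.67 and 6.20.

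The comparison asked what prenatal fluoxetine changed in the adult prelimbic transcriptome, and the series title puts the question on inhibitory synapses. As lists fixed beforehand, activity-regulated immediate early genes, chaperones and clock genes stood higher on the fluoxetine arrays, with median log2 differences of 0.12, 0.11 and 0.05. These calls were made by a list test with a preset correlation, whose degrees of freedom come from the number of genes and not of arrays. Its p-values therefore do not measure the variation between mice. With an estimated correlation, where the test also rests on the 2 residual degrees of freedom, the adjusted p was 0.810, 0.654 and 0.654. At an unadjusted p below 0.05, 19 of the 37, 13 of the 23 and 12 of the 16 members did not pass. The poly-A control transcripts added to the samples before labelling were also higher on both fluoxetine arrays, by a median of 0.24 with 24 of 24 probe sets higher. These probe sets are repeated readings of a few spiked RNAs. The 3' minus 5' signals of the 4 mouse control transcripts went both ways: Actb and Gapdh differed by −0.09 and −0.04, with the nearest arrays of the groups both at −0.286 for Gapdh, and Tfrc and Pcx by 0.15 and 0.14 with overlapping groups. Klf4, a zinc-finger transcription factor, was 1.63-fold higher (log2 difference 0.71, SE 0.08, n = 2 and 2). Fosl2, of the AP-1 family, was 1.44-fold higher (log2 difference 0.53, but 0.04 with its other probe set). Per2, a core repressor of the circadian clock, had a log2 difference of 0.59 (−0.06 to 0.63 over its 3 probe sets). Bhlhe40, a repressor that also acts on the clock, was 1.35-fold higher. No single gene passed the correction for 18193 tests in the limma fit: 0 genes had an adjusted p below 0.05, the lowest adjusted p was 0.335 (Klf4, Ier5 and Bhlhe40), and 1266 genes had an unadjusted p below 0.05, against about 910 by chance. Of these, 628 were higher and 638 lower with fluoxetine, and 92 differed at least 1.5-fold (25 higher, 67 lower; 35 and 37 after another quantile normalization, 7 and 0 above the median level, 163 and 138 with the most variable probe set of a gene). The higher share of the 1266, 49.6%, was 33.9% after another quantile normalization and 66.2% after subtracting array medians. The count of 1266 was 369 without fluoxetine replicate 1, the 92 became 138 to 291 with an array left out, and 85 of the 92 had a mean level below the median of all genes, where a fold depends most on how background was corrected.

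Activity-regulated immediate early genes, a list fixed before the data were examined, rose as a group (limma's camera with a preset correlation, adjusted p = 1.33e-09; median log2 difference 0.12 over 37 members). With an estimated correlation the adjusted p was 0.810. The preset test also called this list when fluoxetine replicate 1 and untreated replicate 1 were set against the other arrays. That split, which mixes the groups, called 13 lists in all. At an unadjusted p below 0.05, 13 members were higher, 5 were lower and 19 did not pass. These counts were 14 and 2 without fluoxetine replicate 2, where the median was 0.18, 9 and 4 without fluoxetine replicate 1 (median 0.09), 15 and 5 without untreated replicate 1 and 13 and 3 without untreated replicate 2. After Benjamini-Hochberg adjustment, 14 members passed adjusted over the list alone and 0 over all genes tested. The log2 differences of the members with the smallest p were 0.71 for Klf4, 0.53 (SE 0.08) for Fosl2, 0.50 (SE 0.08) for the orphan nuclear receptor Nr4a3 and 0.41 (SE 0.05) for Ier5. Bdnf, the neurotrophin whose transcription follows neuronal activity, stood at 9.56 ± 0.08 (SD, n = 2) with fluoxetine and 9.20 ± 0.04 (SD, n = 2) without. Its other probe set differed by only 0.07 and that of Fosl2 by 0.04, while the 2 probe sets of Klf4 differed by 0.65 and 0.71. The list did not move as one block. Btg2, an antiproliferative early gene, had a difference of −0.35 and the matricellular gene Ccn1 one of −0.41. Among common activity markers, Fos differed by 0.06 (SE 0.06), Arc by 0.12 (SE 0.06) and Npas4, an activity-dependent regulator of inhibitory synapses, by −0.14 (SE 0.10), with Fos at −0.02 without untreated replicate 2. Egr1 and Egr3, named after their values were seen, differed by 0.20 (SE 0.07) and 0.29 (SE 0.06), with both fluoxetine arrays above both untreated arrays.

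Heat shock proteins and chaperones rose as a group (camera, adjusted p = 1.02e-09; median log2 difference 0.11 over 23 members), with an adjusted p of 0.654 with an estimated correlation. At an unadjusted p below 0.05, 10 members were higher, 0 lower and 13 did not pass; 5 passed adjusted over the list alone and 0 over all genes tested. The 10 became 3 without fluoxetine replicate 1, 7 to 9 without each other array and 5 without the intensity trend, with 0 lower in each, and the median was 0.20 with the most variable probe sets. Hspa1b, an inducible cytosolic Hsp70, was 1.40-fold higher (log2 difference 0.49, SE 0.13). The small heat shock protein gene Hspb1 differed by 0.31 (SE 0.06), the co-chaperone Dnajb5 by 0.30 (SE 0.05) and Hspa5, the Hsp70 of the endoplasmic reticulum, by 0.22 (SE 0.05). The poly-A controls were 0.24 higher on the same arrays, and the 3' minus 5' signals went both ways. Among the 23 members, 15 had both fluoxetine arrays above both untreated arrays and 0 had the opposite arrangement. Chance alone gives each arrangement in 16.7% of genes, and over all 18193 genes 2814 were higher on both fluoxetine arrays and 4062 lower. Genes above the median level leaned upward instead: in a limma fit of these alone, 523 were higher and 208 lower at an unadjusted p below 0.05.

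Circadian clock genes rose by a smaller amount (camera, adjusted p = 6.95e-05; median 0.05 over 16 members). The adjusted p was 0.654 by camera with an estimated correlation and 0.0195 with fry, which passed for this list alone among the 31. The estimated correlation of this list was −0.06, below the preset 0.01, so that correlation between members did not end its camera call. The 4 members at an unadjusted p below 0.05 were all higher, and the same number passed adjusted over the list alone against 0 over all genes: Per2 (0.59, SE 0.10), Bhlhe40 (0.44, SE 0.05), Cry1 (0.29, SE 0.08) and Per1 (0.27, SE 0.06). The other 12 did not pass. The median was 0.08 without untreated replicate 2, 0.09 after subtracting array medians, and 0.10 and 0.11 with the mean and the most variable probe sets. The poly-A controls, 0.24 higher, stood beside this list and the next. Glucocorticoid-responsive genes, which share Per1 with both lists, also rose (adjusted p = 0.0103; median 0.04 over 17 members; adjusted p = 0.843 with an estimated correlation). Of these, 5 were higher, 1 was lower and 11 did not pass at an unadjusted p below 0.05, and 3 passed adjusted over the list alone against 0 over all genes. Their leading members were Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein (0.30, SE 0.05; −0.21 to 0.38 over its 4 probe sets), Per1, the kinase gene Sgk1 (0.23, SE 0.06) and Errfi1 (0.18, SE 0.06). The glucocorticoid call ended without fluoxetine replicate 2 (median 0.01, adjusted p = 0.0902) and without untreated replicate 1 (median 0.04, adjusted p = 0.147). It held at larger medians without fluoxetine replicate 1 (0.09, adjusted p = 0.000284) and without untreated replicate 2 (0.11, adjusted p = 0.0133), and at 0.0028 after another quantile normalization (adjusted p = 0.0346).

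**Figure D1:**
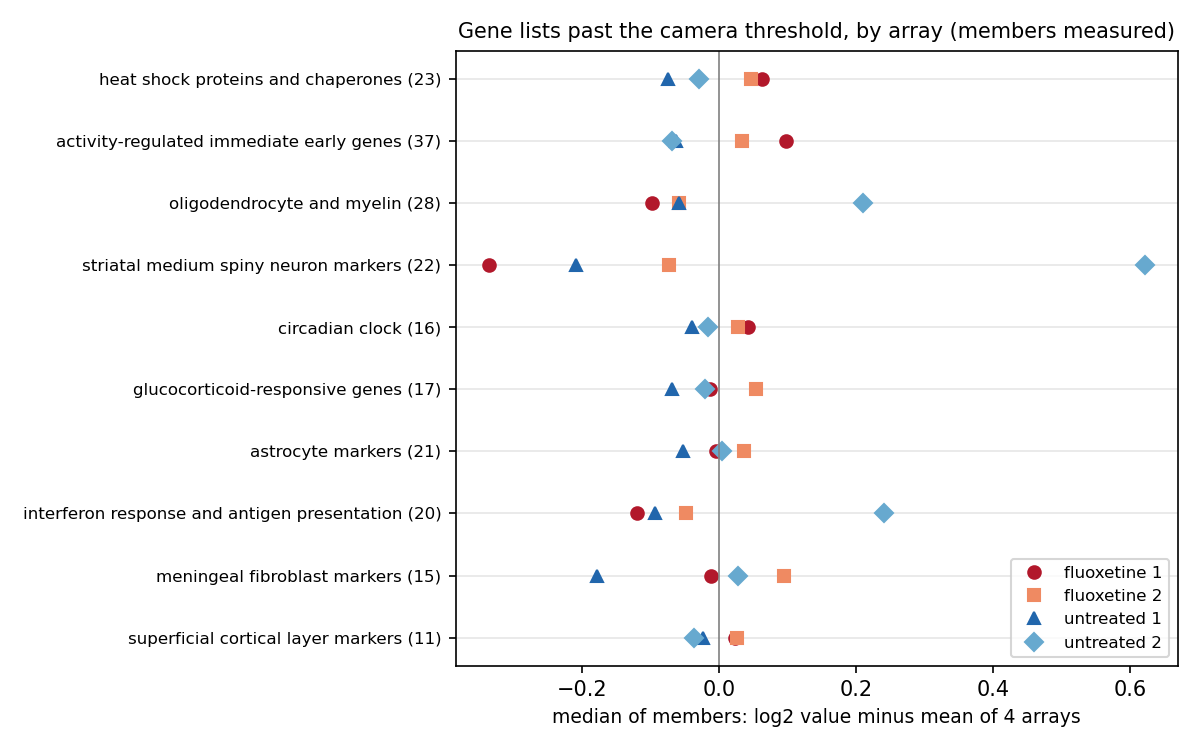
Per-array level of the 10 gene lists past the camera threshold; each point is 1 array's median over the list's members of the log2 value minus that gene's mean over the 4 arrays, with the number of members in brackets. For chaperones the fluoxetine arrays lie at 0.06 and 0.05 and the untreated arrays at −0.07 and −0.03, while for striatal markers untreated replicate 2 stands apart at 0.62.

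Genes that mark inhibitory neurons and synapses did not pass as groups. The list of GABA synthesis, transport and receptor genes had an adjusted p of 0.238 (median 0.03 over 15 members; 1 higher, 0 lower), scaffold and adhesion proteins of the inhibitory synapse one of 0.584 (median −0.05 over 13 members; 1 higher, 0 lower), interneuron markers one of 0.573 (median −0.00 over 26 members; none at an unadjusted p below 0.05) and perineuronal net genes one of 0.299 (median 0.03 over 11 members; none). The GABA list passed without untreated replicate 2 (median 0.10, adjusted p = 0.0139). It also passed with other choices of probe set, namely the mean of all of a gene's probe sets (median 0.09, adjusted p = 0.00586) and the most variable of them (median 0.14, adjusted p = 0.00808). Gad1 and Gad2, the GABA-synthesizing enzymes, differed by 0.06 (SE 0.04) and −0.00 (SE 0.09). Gad2 was at 0.03 after subtracting array medians. Each gene had 2 probe sets, and the other one differed by 0.24 for Gad1 and by 0.49 for Gad2. The interneuron genes Sst and Vip differed by −0.10 (SE 0.05) and 0.09 (SE 0.07). The Vip difference rested on untreated replicate 2, at 11.07 against 11.25 to 11.26 on the other arrays, and was −0.0040 without it. Pvalb, the calcium-binding protein of fast-spiking interneurons, differed by 0.40 (SE 0.25), which rested on fluoxetine replicate 1 at 11.17 against 10.25 to 10.36 on the other arrays; without that array it was −0.05. The inhibitory scaffold gene Gphn differed by 0.03 (SE 0.06), or −0.01 after another quantile normalization, and the adhesion gene Nlgn2 by −0.06 (SE 0.05).

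The serotonin system list had an adjusted p of 0.634 (median −0.01 over 21 members; 0 higher, 1 lower and 20 not past an unadjusted p of 0.05). Slc6a4, the serotonin transporter that fluoxetine blocks, lay at 5.66 ± 0.03 (SD, n = 2) with fluoxetine and 5.85 ± 0.19 (SD, n = 2) without, below the median of 7.87 over all genes. The receptor genes Htr1a and Htr3a differed by −0.03 (SE 0.08) and 0.11 (SE 0.17), with Htr1a at 0.01 after subtracting array medians. Htr2c differed by −0.31 (SE 0.21) because untreated replicate 2 stood at 10.26 against 9.46 to 9.70 elsewhere, and the difference was 0.06 without that array; Htr3a moved to −0.17 without it.

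Markers of striatum, which borders the medial prefrontal cortex, and of myelin fell with fluoxetine, and both calls rested on 1 untreated array; with an estimated correlation both had an adjusted p of 0.843. Striatal medium spiny neuron markers had a median difference of −0.36 over 22 members (camera, adjusted p = 1.22e-05), with 0 higher, 2 lower and 20 not past an unadjusted p of 0.05, and 0 members passed adjusted over the list alone or over all genes. Rgs9, a regulator of dopamine signalling in striatum, read 10.18 in untreated replicate 2 against 8.94 to 9.28 on the other arrays, and Syndig1l 7.00 against 5.84 to 6.21. Without untreated replicate 2 the list's median was 0.00 (adjusted p = 0.881), with 1 member higher and 1 lower; without untreated replicate 1 it was −0.75 with 19 lower. Oligodendrocyte and myelin genes had a median of −0.15 over 28 members (adjusted p = 5.77e-06), with 0 higher, 5 lower and 23 not past an unadjusted p of 0.05, and 0 passed adjusted over the list alone or over all genes. The 5 lower members became 14 after another quantile normalization (median −0.17) and 1 without the intensity trend, with 0 higher in each. The myelin genes Mag (−0.24, SE 0.08), Fa2h (−0.25, SE 0.09) and Pllp (−0.26, SE 0.07) and the oligodendrocyte transcription factor Sox10 (−0.26, SE 0.08) led the list. Its median without untreated replicate 2 was −0.02 (adjusted p = 0.478), with 2 members higher and 1 lower, and without untreated replicate 1 −0.28 with 22 lower. Interferon response and antigen presentation genes had a median of −0.14 over 20 members (adjusted p = 0.0103; 0.843 with an estimated correlation), with 0 higher and 1 lower, Tap1 (−0.33, SE 0.13). None passed adjusted over the list alone or over all genes. Ifit1 read 6.83 in untreated replicate 2 against 5.53 to 5.71 elsewhere. The list's call ended without that array (median −0.01, adjusted p = 0.939) and without fluoxetine replicate 1 (median −0.12, adjusted p = 0.155), while without untreated replicate 1 the median was −0.29 with 9 lower. It also ended without the intensity trend (adjusted p = 0.0898) and with the most variable probe sets (adjusted p = 0.0766).

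Astrocyte, meningeal and superficial-layer markers passed camera with small positive medians, and the astrocyte median was −0.0027 after another quantile normalization. With an estimated correlation the adjusted p was 0.843 for astrocyte and meningeal markers and 0.810 for superficial-layer markers. At an unadjusted p below 0.05, 3 of 21, 2 of 15 and 1 of 11 members were higher. Beside these lists too, the poly-A controls were 0.24 higher on the fluoxetine arrays. Astrocyte markers had a median of 0.03 over 21 members (adjusted p = 0.0103), with 1 lower and 17 not past an unadjusted p of 0.05; 1 passed adjusted over the list alone and 0 over all genes. The gap junction gene Gjb6 (0.30, SE 0.05) and the glutamate transporter gene Slc1a3 (0.21, SE 0.06) were higher and the sodium pump subunit gene Atp1b2 lower (−0.15, SE 0.04). Meningeal fibroblast markers had a median of 0.09 over 15 members (adjusted p = 0.0107), with 2 higher, Dcn (0.23, SE 0.08) and Col1a2 (0.20, SE 0.08), and 0 lower. The 3 probe sets of Col1a2 ran from −0.83 to 0.20. Superficial cortical layer markers had a median of 0.07 over 11 members (adjusted p = 0.0207), with 1 higher, the upper-layer transcription factor Cux2 (0.17, SE 0.05), and 0 lower. In both of these lists 0 members passed adjusted over the list alone or over all genes. The astrocyte and meningeal calls ended without fluoxetine replicate 2 (medians 0.01 and 0.03, adjusted p = 0.254 and 0.236) and without untreated replicate 1 (medians 0.01 and 0.05, adjusted p = 0.251 and 0.497). Without untreated replicate 2 their medians were larger, 0.06 (adjusted p = 0.00444) and 0.23 (adjusted p = 0.000331, with 7 meningeal members higher), and without fluoxetine replicate 1 they were 0.05 and 0.12. The superficial-layer call ended without fluoxetine replicate 2 (median 0.04, adjusted p = 0.113) and without untreated replicate 2 (median 0.06, adjusted p = 0.248). Another quantile normalization ended the astrocyte (adjusted p = 0.160) and superficial-layer calls (adjusted p = 0.137), as did a fit without the intensity trend (adjusted p = 0.0568 and 0.0736). A filter at the median level ended the superficial-layer call (adjusted p = 0.0594), and the mean or the most variable probe set ended the meningeal one (adjusted p = 0.158 and 0.213).

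By size alone, in or out of the lists, the largest difference among genes above the median level with separated groups and an unadjusted p below 0.05 was that of Malat1, an abundant nuclear noncoding RNA, at 11.29 ± 0.42 (SD, n = 2) with fluoxetine and 10.32 ± 0.14 (SD, n = 2) without, 1.97-fold (log2 difference 0.98, SE 0.17; limma adjusted p = 0.666). All 7 of its probe sets were higher with fluoxetine, by 0.05 to 1.05, and the poly-A controls were 0.24 higher on the same arrays. Apart from Klf4, Per2 and Fosl2, given above, next came the phosphodiesterase gene Pde1a (0.72, SE 0.26), Creg2 (0.70, SE 0.20), Zbtb7a (0.66, SE 0.20), the imprinted noncoding RNA Ipw (0.61, SE 0.09), Nlgn1 (0.55, SE 0.21), an adhesion gene of the postsynaptic density list, Ankrd12 (0.54, SE 0.13), Ccar1 (0.53, SE 0.12) and the mRNA export factor gene Fyttd1 (0.53, SE 0.08). Another probe set of the gene gave −0.02 for Pde1a, −0.19 for Zbtb7a, −0.08 for Nlgn1, −0.0013 for Ankrd12, −0.19 for Ccar1 and −0.03 for Fyttd1. Among lower genes the differences were smaller, from −0.41 for Ccn1 of the immediate early list to −0.31 for Gal3st1, an enzyme of myelin sulfatide synthesis. Between them lay, among others, the protein kinase gene Prkch (−0.36, SE 0.14), Btg2 of the same early gene list, the chemokine gene Cxcl1 (−0.34, SE 0.13), Nfkb2 of the NF-kappaB family (−0.33, SE 0.10), Supt20 (−0.31, SE 0.08), the phosphoinositide kinase gene Pik3cd (−0.31, SE 0.10) and Lgals3bp (−0.31, SE 0.10). Of the 7 Supt20 probe sets, 2 shared that sign, and those of Pik3cd ran up to 0.22. Over all named genes, 26 of the 50 with several probe sets had at least 1 of the opposite sign. Among the list members named above these include Nr4a3 (−0.11), Per2 (−0.06), Hspa5 (−0.08), Slc1a3 (−0.21) and Tap1 (0.30).

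**Figure D2:**
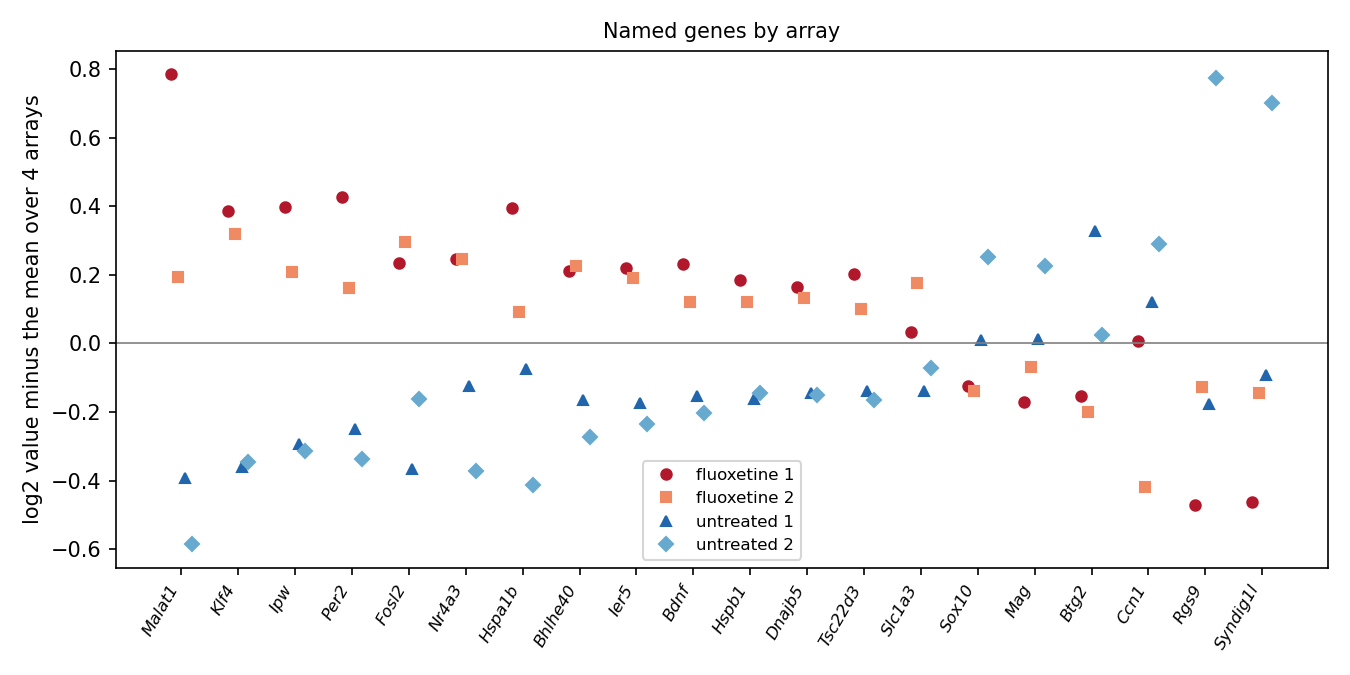
Log2 value minus the mean over the 4 arrays for 20 named genes; each point is 1 array. Klf4 lies at 8.27 and 8.34 with fluoxetine against 7.59 and 7.61 without, while for Rgs9 untreated replicate 2 stands apart from the other 3 arrays at 10.18.

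The remaining 16 lists had adjusted p-values from 0.0952 to 0.988 by camera, which compares a list with all other genes. Microglia markers (median −0.07, adjusted p = 0.0952) and dopamine and noradrenaline receptors (median −0.16, adjusted p = 0.0952) came nearest, followed by glutamate receptors (median 0.00, adjusted p = 0.147), cytosolic ribosomal proteins (median −0.04, adjusted p = 0.170), endothelial and pericyte markers (median 0.03, adjusted p = 0.299), the excitatory postsynaptic density (median −0.03, adjusted p = 0.418) and neuropeptides (median −0.04, adjusted p = 0.501). Blood cell transcripts (adjusted p = 0.503), immature neuron markers (0.634), thalamic and deep-layer markers (both 0.767), choroid plexus, synaptic vesicle, respiratory chain and oligodendrocyte precursor genes (all 0.880) and voltage-gated ion channels (0.988) completed them. For 8 of the 21 lists that did not pass, the postsynaptic density, interneuron, serotonin, immature neuron, thalamic, choroid plexus, respiratory chain and oligodendrocyte precursor lists, the camera direction was up while the median was below 0.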

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

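The array's poly-A control transcripts, bacterial RNAs that are added to a sample before labelling and belong to no mouse gene, took part in no comparison. Their signal was higher on both fluoxetine arrays than on both untreated arrays. The median log2 difference over their 24 probe sets was 0.24, and all 24 were higher with fluoxetine. These probe sets read only a few spiked RNAs (dap, lys, phe and thr), so they are repeated readings and not 24 separate results. Relative to the mean over the 4 arrays, the medians were 0.06 and 0.17 with fluoxetine and −0.21 and −0.05 without. The hybridization control transcripts, which are added after labelling, had a median difference of 0.05 over 18 probe sets, of which 15 were higher with fluoxetine, with overlapping groups.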

How the results depend on the processing

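The settings were chosen before the data were examined, except the one that leaves out 2 arrays together and the counts of list members with an array left out. No named gene passed an adjusted p of 0.05 under any setting, and 62 of the 75 named genes kept their sign under every one. The count of genes at an adjusted p below 0.05 was 0 in the main analysis and with the other fits and scalings. It was 1 with the most variable probe set of a gene and with all probe sets (Homer1 in both), and 0 to 1 when each array was left out in turn (the 1 was Gt(ROSA)26Sor); the genes were noted after their values were seen. Genes at an unadjusted p below 0.05 numbered 1266, against 731 above the median level, where fewer genes were tested, 3959 for all probe sets, where more were, and 369 to 1716 with an array left out. The 92 genes at least 1.5-fold apart became 7 above the median level, 301 with the most variable probe set, 440 with all probe sets, 681 at 1.2-fold, 1 at 2-fold and 138 to 291 with an array left out. Of the genes at an unadjusted p below 0.05, 49.6% were higher, against 33.9% after quantile normalization, 66.2% after subtracting array medians, 30.0% without the trend and 71.5% above the median level. Of the 92, 85 lay below the median level, where signal over background is low. The 10 lists became 0 with an estimated correlation and 1 with fry, and 7 to 13 with the other fits, scalings and probe set choices. Immediate early genes, chaperones and clock genes were called in all 8 of these. Robust estimation does not enter camera, so that this setting only repeated the main list calls. Array weights were the same for both arrays of a group (1.25 with fluoxetine, 0.80 without), so they could not discount a single array. With an array left out, the lowest medians of immediate early, chaperone and clock genes were 0.09, 0.08 and 0.04. Lists called only under some of these settings were those of microglia, GABA, endothelial, synaptic vesicle, ribosomal, dopamine, glutamate receptor, channel and blood cell genes. Where a list was called in the main analysis or in the alternative, medians changed sign for astrocyte markers after quantile normalization (−0.0027), for synaptic vesicle genes with the mean (0.0434) or the most variable (0.11) probe set, and for voltage-gated channels with the latter (0.0347). Striatal markers ranged from −0.75 to 0.0012 with an array left out. Lists called in neither changed sign 53 times in all, over 19 lists. Leaving out fluoxetine replicate 1 and untreated replicate 2 together, the ends of the first principal component, leaves no test; striatal markers were then at 0.11 and interferon genes at 0.0702, immediate early genes at 0.08 and chaperones at 0.14. Where no reason is given, the cause was not tested.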

Other observations

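The tests of other pairings of the arrays, of Homer1 under other settings, of striatal and myelin tissue, of the clock phase and of the 3' to 5' signal were chosen after the results were seen. Those of the gradient and of nuclear RNA were chosen before their own values were seen. The patterns that they address, such as higher Malat1 and Ipw, had been found in these data. Homer1, which encodes both long scaffold proteins of the postsynaptic density and a short form induced by neuronal activity, held the probe set with the lowest adjusted p when all probe sets were tested. It was noted after its values were seen. Of its 6 probe sets, 1 stood at 11.04 and 10.99 with fluoxetine and 9.88 and 9.99 without, a log2 difference of 1.08 (SE 0.06; limma adjusted p = 0.0116 over 45037 probe sets). A dimmer probe set differed by 0.996 (SE 0.17), and the brightest, which stood for the gene in the comparison of genes, by 0.02 (SE 0.04). The remaining 3 differed by 0.17 to 0.40. The difference of 1.08 was 1.03 to 1.13 when an array was left out. Its adjusted p was 0.0022 to 0.584 under the other fits and scalings, failing without the intensity trend, and 0.426 to 1 with an array left out. Which form each probe set reads was not analysed here.

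Excitatory synapse genes, also chosen after their values were seen, held single members with separated groups. Gria2, an AMPA receptor subunit, differed by 0.28 (SE 0.06), the metabotropic receptor gene Grm3 by 0.24 (SE 0.06) and the synaptic adhesion gene Lrrtm2 by 0.29 (SE 0.06), each with both fluoxetine arrays above both untreated arrays. Shank1, a scaffold gene of the postsynaptic density, went the other way, by −0.31 (SE 0.10), with both fluoxetine arrays below. At an unadjusted p below 0.05 the glutamate receptor list held 3 higher and 0 lower members and the postsynaptic density list 5 and 1. After another quantile normalization these counts were 3 and 0 and 4 and 4, and without the intensity trend 2 and 0 and 2 and 1. Of the glutamate receptor list 2 passed adjusted over the list alone and of the postsynaptic density list 1, against 0 over all genes tested. Among deep-layer genes 2 were higher, Fezf2, a determinant of subcortical projection neurons (0.33, SE 0.08), and Tox (0.19, SE 0.08), and 2 lower, Syt6 (−0.44, SE 0.12) and Tle4 (−0.12, SE 0.05), both of corticothalamic neurons.

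The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 1266 genes at an unadjusted p below 0.05, the most of the 3 (1 split with as many), and the highest other split gave 740. It gave 10 lists by camera, and the highest other gave 13, so that 2 of the 3 splits had as many. The split with 13 lists, which pairs arrays of different groups, also called the immediate early genes, with the striatal, myelin, astrocyte, meningeal and interferon lists; the chaperone, clock, glucocorticoid and superficial-layer lists were called in the real split alone. It gave 1 gene at an adjusted p below 0.05, against 0 for the real split, and 87 genes at least 1.5-fold apart, against 92; the other gave 0 and 56. The first principal component of the 9096 brighter genes held 48.1% of their variance, with fluoxetine replicate 1 at 7.88, fluoxetine replicate 2 at 1.42 and the untreated arrays at −2.72 and −6.57.

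For the lower striatal and myelin transcripts in the fluoxetine group, a candidate explanation is that the punch behind untreated replicate 2 took in more striatum and white matter. Without that array no difference was called (striatal median 0.0012, adjusted p = 0.881; myelin median −0.0198, adjusted p = 0.478), but any peculiarity of the array would give the same. Interferon genes, which mark neither tissue, were also 0.32 above the other arrays there, and Gt(ROSA)26Sor, the noncoding transcript of a locus widely used for transgenes, read 11.09 against 8.41 to 8.75, so that a different genotype or another peculiarity of that array stays open beside the tissue. In untreated replicate 2, 20 of 22 striatal and 25 of 28 myelin genes were at their highest, and Penk, the brightest striatal marker, read 12.31 against 10.98 to 11.39; cortex expresses many of these genes too. An effect of prenatal fluoxetine on these transcripts was not detectable without that array, with 1 untreated array left.

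Immediate early genes and chaperones were higher with fluoxetine by camera, with an adjusted p of 0.810 and 0.654 with an estimated correlation; 19 of 37 and 13 of 23 members did not pass an unadjusted p of 0.05, and 5 early genes were lower. A gradient that also parts arrays within groups may contribute: the gap between arrays of a group along a principal component of all other genes was 0.18 of the group difference, with a bootstrap interval of −0.14 to 0.42 over the 60 genes. A different time of day at dissection may contribute as well: the clock genes of the Per and Dbp phase had a median difference of 0.0496 (bootstrap interval −0.02 to 0.18, 10 genes) and those of the opposite phase one of 0.02 over 4 genes, so that neither a phase shift nor its absence was resolved. The poly-A controls (0.24, 24 of 24 probe sets) were also higher on both fluoxetine arrays, but their order within that group was the reverse. On fluoxetine replicates 1 and 2 they stood at 0.06 and 0.17, immediate early genes at 0.10 and 0.03 and chaperones at 0.06 and 0.05. On untreated replicates 1 and 2 the values were −0.21 and −0.05, −0.06 and −0.07, and −0.07 and −0.03. The 3' minus 5' signals went both ways (Actb −0.09, Gapdh −0.04, Tfrc 0.15, Pcx 0.14), and a difference in RNA input or quality stays open too. So do prenatal fluoxetine itself and handling before dissection, of which the labels record nothing.

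Malat1 and Ipw, both noncoding RNAs, were higher with fluoxetine. A larger share of nuclear RNA would raise nuclear transcripts alike. Over 23 other nuclear-retained and intron-detaining transcripts the median difference was 0.0390 (bootstrap interval over genes 0.00 to 0.17). Malat1 differed by 0.98 and Ipw by 0.61. Within that set, 11 nuclear long noncoding RNAs had a median of 0.0013 (from −0.09 for Rian to 0.23 for Miat and 0.24 for Snhg11). Both fluoxetine arrays lay above both untreated arrays for 2 of them and below for 2. These noncoding RNAs argue against a larger nuclear share as the whole cause. The 12 splicing regulators with detained introns had a median of 0.12, with 7 separated higher and 1 lower. Over all genes 15.5% were separated higher. Their probe sets were not chosen for the detained introns, so a smaller nuclear contribution stays open. Whether a different 3' to 5' balance of the RNA plays a part was not resolved. Of the 4 mouse control transcripts, Actb and Gapdh had lower 3' minus 5' signals with fluoxetine (by −0.09 and −0.04). For Gapdh the nearest arrays of the groups were both at −0.286. Tfrc and Pcx differed by 0.15 and 0.14 with overlapping groups. Chance alone separates the groups in 33.3% of genes, so that 2 of 4 decides nothing. An effect of prenatal fluoxetine stays open and was not tested apart from these.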
